A study of Homo sapiens with 12 samples.

How the data were processed

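RNA was measured in 12 libraries of 2 human medulloblastoma cell lines, ONS76 and DAOY, each static or under fluid shear stress (FSS) for 18 h, with 3 libraries in each of 4 groups. Groups and replicate numbers were taken from the sample titles. Per the labels' protocols, total RNA with an integrity number above 9.8 was made into directional polyA libraries and sequenced as paired 100 bp reads, with 30 M paired-end reads stated per sample. Per the submitters' processing notes, reads were aligned with HISAT2 2.2.1 to GRCh38 and counted with featureCounts, whose version is not given. The annotation and the strand and overlap settings of the counting are not given in the sources used here.

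The authors deposited a table of raw counts per gene (63241 genes, 42640 with a symbol) and a table of TPM values for the same genes and libraries. Library totals in the count table ran from 38.1 to 49.3 M. They lie above the 30 M stated, and whether a count is a read or a pair is not given. TPM values matched the deposited counts divided by 1 length per gene and scaled per library, within 0.1% for 100% of 28646 genes that could be compared, so the TPM table carries no independent measurement. Reads of overlapping genes, antisense partners and near-identical copies may not be assigned to the gene they came from, and a count of 0 in all libraries need not mean that a gene is silent.

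Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with the design (19631 genes, 16860 with a symbol, holding 99.96% of counts), library sizes were scaled by TMM, and quasi-likelihood models with 1 mean per group were fitted to all 12 libraries, so that groups share an estimate of the spread. Contrasts were FSS minus static in each line, the difference of these responses (DAOY minus ONS76), and static ONS76 minus static DAOY. Tests were two-sided, with Benjamini-Hochberg adjusted p under 0.05 over all tested genes as the threshold. Standard errors are the absolute log2 fold change divided by the square root of the quasi-likelihood F. Fitted fold changes use edgeR's prior count of 0.125, so for a gene at 0 in a group a lower bound is given against a floor of 3 counts over the group. The common biological coefficient of variation was 4.87%. With 3 libraries against 3 there are 10 splits, so a share of splits cannot go under 0.1.

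Before the data were examined, 42 gene lists, the alternatives and the rule for named genes were fixed. The rule took, per line, the 10 genes with the largest rise and the 10 with the largest fall among called genes at 5 CPM or more in the higher group whose FSS and static libraries do not overlap. It also took 5 per direction in both lines together and for the difference of responses, 5 per direction between static lines at 50 CPM or more, up to 4 members of each list by smallest p in each line, and 12 genes chosen beforehand (among them PIEZO1, PIEZO2, KLF2, KLF4, CCN1, CCN2, SLC2A1, VEGFA, MYC, GLI1 and FOS). Results of 1 of these genes, of 1 other gene that the rule takes and of 1 gene list are not reported here. Features with no symbol were not named. Some of the genes that the rule takes are summarised as ranges. Lists with at least 5 tested members were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry, which asks whether a list's genes move on balance in 1 direction, were run beside it. Ranges of adjusted p over the alternatives of a list leave out fry. Testing lists for the difference between the lines was added after the data were seen. Short lists of cold-inducible, tonicity-responsive and heart muscle genes were written after the data were seen and enter the closing tests alone. Members are counted as called over all genes and, separately, adjusted over the list alone.

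Alternatives were a replicate block, DESeq2 1.42.0, RLE and upper-quartile scaling factors, no filter, a stricter filter, fits of each line alone, limma on log2 TPM with pseudocounts of 1 and 0.1, and leaving out each library in turn. Leaving out static ONS76 libraries 1 and 2 was added after the data were seen. Gene coordinates are from GENCODE 29 on GRCh38, which matched 18591 of the tested genes by identifier. It may not be the annotation behind the counts.

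The edgeR test was tried on simulated counts drawn from the real means and library sizes, with 200 genes changed among 19273 tested. For ONS76 it recovered 68%, 60%, 94% and 90% of 50 genes changed by 1.25, 1.5, 2 and 4 fold, and for DAOY 62%, 82%, 92% and 98%. False calls were 10 of 166 (6.02%) in ONS76 and 7 of 187 (3.74%) in DAOY. A list planted in DAOY was called and no other list was. Simulated genes were drawn independently of each other, so this does not show how often lists are falsely called when their genes move together. A far larger share of genes was called in the data (28.0% in ONS76 and 39.7% in DAOY), so the simulated rates need not hold there. In the data the estimated correlation within lists ran from -0.0460 (Wnt pathway genes) to 0.953 (mitochondrially encoded mRNAs). Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.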

Results

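The series measured polyadenylated RNA in ONS76 and DAOY, established human cell lines grown from medulloblastoma, a childhood tumour of the cerebellum. Both lines were kept in artificial cerebrospinal fluid in 6-well plates. Plates were either left static or turned on an orbital shaker at 100 rpm for 18 hours, which drives the fluid over the cells and exposes them to fluid shear stress (FSS). Every plate under FSS was shaken and static plates were not. Changes under FSS are therefore those of shaken against static plates, and shear cannot be told apart from other effects of the shaker. Each of the 4 groups held 3 libraries described as biological replicates. Nothing given here says how the replicate cultures were separated, so p-values measure the spread between these libraries. The comparisons ask how each line's transcripts respond to FSS, which responses the lines share, and where they differ.

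Library depth was 41.4 to 45.4 M counts (1 M is 1e6) in ONS76 under FSS, 39.4 to 49.3 M in static ONS76, 39.2 to 44.7 M in DAOY under FSS and 38.1 to 41.0 M in static DAOY. Of 63241 genes in the table, 31149 had at least 1 count and 19631 entered the tests. Within groups the median coefficient of variation of genes at 5 CPM (counts per 1e6) or more was 3.88% to 4.19%. No 2 replicates were alike within sampling noise, as their counts differed by 3.59 to 8.57 times the chi-square value that counting alone gives per degree of freedom. Line identity was the main axis of variation: the first principal component held 90.5% of the variance and separated ONS76 from DAOY. The second held 2.87%, with all 6 FSS libraries between -34.8 and -20.1 and all 6 static libraries between 20.1 and 38.4. On the fourth component the static ONS76 libraries stood apart from each other, at 41.6 for replicate 3 against -17.9 and -31.4 for replicates 1 and 2. These components describe the samples and carry no test.

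The transcriptome of ONS76 changed broadly under FSS and mostly by small amounts. The largest rise under the rule for named genes was in ARRB1, which encodes the receptor adaptor beta-arrestin 1 (ENSG00000137486, chromosome 11, 75264182 to 75351705 in GRCh38), at a log2 fold change of 2.19 (SE 0.13), from 2.17 ± 0.217 CPM to 9.94 ± 1.64 CPM (mean and SD, n = 3). Also among the largest rises were BMP7, a secreted bone morphogenetic protein, at 1.77 (SE 0.12), AKR1C1, a steroid- and aldehyde-reducing enzyme, at 1.54 (SE 0.10), and IGFBP5, an insulin-like growth factor binding protein, at 1.39 (SE 0.057). Among the largest falls were RBM3, a cold-inducible RNA-binding protein (chromosome X, 48574449 to 48579066), at -1.57 (SE 0.041), the calcium-binding S100P at -1.23 (SE 0.12), IGFBP3 at -1.22 (SE 0.12) and NAGLU, a lysosomal enzyme, at -1.22 (SE 0.20). AQP3, a water and glycerol channel, rose from 9.13 ± 0.999 CPM to 25.8 ± 0.992 CPM, and the interferon-induced OASL fell from 10.7 ± 0.543 CPM to 3.75 ± 0.783 CPM. Adjusted p for these 10 genes ranged from 1.51e-23 (RBM3) to 1.24e-05 (NAGLU), and the 3 FSS libraries did not overlap the 3 static ones in any of them. Non-overlap was part of the rule that named them and arises by chance for 10% of genes. AKR1C1 can exchange reads with its near-identical neighbours in a gene family, so its value is uncertain.

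In all, 2770 genes rose and 2735 fell in ONS76 among 19631 tested (edgeR, adjusted p under 0.05), and 344 and 320 of them by 2-fold or more. The called genes were 28.0% of those tested, and their median absolute log2 change was 0.32. Leaving out static ONS76 libraries 1 and 2, in which the cardiac myosin transcripts MYH6 and MYH7 stood apart, left 1558 risen and 1818 fallen genes. In that fit, chosen after the data were seen, 1 static library stands for the group and is assumed to vary like the others. That library, replicate 3, differed most within its group. Its counts lay at 8.57 and 7.21 times the chi-square value of counting alone from replicates 1 and 2, which lay at 3.59 from each other. Calls lost in that fit therefore cannot be traced to libraries 1 and 2.

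Chaperone genes rose together in ONS76. In the heat shock list 12 of 14 tested members rose and 0 fell, or 12 and 0 when adjusted over the list alone (camera adjusted p = 1.32e-10, and adjusted p = 0.147 with an estimated correlation). The cochaperone HSPH1 rose by 0.98 (SE 0.039), the cytosolic chaperone HSP90AA1 by 0.91 (SE 0.037) and HSPA1A by 0.93 (SE 0.043). HSPA1A and HSPA1B are near-identical and can exchange reads. In the unfolded protein response list 15 of 20 tested members rose and 1 fell, or 15 and 1 when adjusted over the list alone (camera adjusted p = 2.15e-06, and adjusted p = 0.170 with an estimated correlation). Its members HSPA5, the main chaperone of the endoplasmic reticulum, HSP90B1 and the transcription factor XBP1 rose by 0.43 (SE 0.039), 0.40 (SE 0.039) and 0.41 (SE 0.043), while EDEM1, which directs misfolded glycoproteins to degradation, fell, at -0.45 (SE 0.040).

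Genes of ion and solute transport, of the TGF-beta and BMP response and of the extracellular matrix also rose in ONS76. Among ion and solute carriers 16 of 24 tested members rose and 2 fell, or 16 and 2 when adjusted over the list alone (camera adjusted p = 0.000306, and adjusted p = 0.305 with an estimated correlation). Besides AQP3, the sodium pump subunit ATP1B1 rose by 0.64 (SE 0.049) and the sorbitol-producing enzyme AKR1B1 by 0.56 (SE 0.047), and the taurine transporter SLC6A6 fell, at -0.50 (SE 0.051). Among TGF-beta and BMP targets 11 of 23 tested members rose and 2 fell, or 11 and 2 when adjusted over the list alone (camera adjusted p = 0.00399, and adjusted p = 0.147 with an estimated correlation). The ligand BMP4 rose by 1.19 (SE 0.16), the inhibitory SMAD6 by 0.87 (SE 0.070) and PMEPA1 by 0.50 (SE 0.038). In the extracellular matrix list 12 of 30 tested members rose and 4 fell, or 12 and 4 when adjusted over the list alone (camera adjusted p = 0.0498, and adjusted p = 0.362 with an estimated correlation). Versican (VCAN) rose by 1.21 (SE 0.077) and perlecan (HSPG2) by 0.51 (SE 0.040), and the collagen chain COL5A1 fell, at -0.68 (SE 0.040). The matrix call sat at the threshold: it was lost with a replicate block (adjusted p = 0.104) and with a stricter filter (0.0732). It was also lost without any 1 of DAOY FSS replicate 3, DAOY static replicates 1, 2 and 3, ONS76 FSS replicates 1 and 3, or ONS76 static replicate 3 (0.0525 to 0.0910). Over all its alternatives the adjusted p ran from 0.0176 to 0.362.

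Cell-cycle genes fell together in ONS76. In the G2/M and mitosis list 0 of 31 tested members rose and 31 fell, or 0 and 31 when adjusted over the list alone (camera adjusted p = 3.84e-23, and adjusted p = 0.147 with an estimated correlation). Topoisomerase TOP2A fell by 0.65, the mitotic kinases CDK1 and AURKB fell by 0.71 and 0.76, and the kinesin KIF2C fell by 0.77 on the log2 scale, with SEs of 0.037 to 0.055. In the G1/S and DNA replication list 0 of 28 tested members rose and 23 fell, or 0 and 23 when adjusted over the list alone (camera adjusted p = 3.34e-15, and adjusted p = 0.0846 with an estimated correlation). RRM2, a subunit of ribonucleotide reductase, changed by -0.76 (SE 0.047), the replicative helicase subunit MCM6 by -0.68 (SE 0.047) and the transcription factor E2F1 by -0.76 (SE 0.063). MYC changed by -0.17 (SE 0.045), with adjusted p = 0.00367, a call lost when TPM values were tested (adjusted p = 0.137 with a pseudocount of 0.1, and 0.000282 to 0.137 over all alternatives).

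Interferon-stimulated genes, respiratory chain genes, YAP/TAZ targets and glycolytic genes fell as groups in ONS76. Of the interferon-stimulated genes 0 of 20 tested members rose and 10 fell, or 0 and 12 when adjusted over the list alone (camera adjusted p = 4.6e-05, and adjusted p = 0.0846 with an estimated correlation). Besides OASL, IFI35 changed by -1.07 (SE 0.097), ISG15 by -0.68 (SE 0.080) and the virus-tethering protein BST2 by -1.34 (SE 0.16). IFIT1, IFIT2, IFIT3, OAS2, OAS3 and CXCL10 of this list were at 0 in all 12 libraries and were not tested. In the oxidative phosphorylation list 0 of 26 tested members rose and 13 fell, or 0 and 15 when adjusted over the list alone (camera adjusted p = 0.0002, and adjusted p = 0.449 with an estimated correlation), with complex subunits UQCRC1, CYC1 and NDUFV1 each at -0.36. Of the YAP/TAZ targets 1 of 27 tested members rose and 11 fell, or 1 and 13 when adjusted over the list alone (camera adjusted p = 0.00106, and adjusted p = 0.305 with an estimated correlation). ANKRD1 changed by -1.79 (SE 0.17), CCN1 by -0.79 (SE 0.069) and IGFBP3 as above, while the ectonucleotidase NT5E rose by 0.45 (SE 0.040). CCN2 was listed at 0 in all 12 libraries and was not tested. In the glycolysis list 1 of 22 tested members rose and 12 fell, or 2 and 13 when adjusted over the list alone (camera adjusted p = 0.0344, and adjusted p = 0.449 with an estimated correlation). PDK1, a kinase of pyruvate dehydrogenase, changed by -1.16 (SE 0.095), ENO1 by -0.23 (SE 0.037) and LDHA by -0.20 (SE 0.041). The glycolysis call was lost with a replicate block (adjusted p = 0.0591) and without ONS76 static replicate 1 (0.0648) or replicate 3 (0.0529), with 0.00984 to 0.449 over all alternatives.

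In DAOY, signalling, inflammatory and angiogenic genes and chaperones rose under FSS, and replication and lipid synthesis genes fell. TNFSF15, a cytokine of the tumour necrosis factor family (ENSG00000181634, chromosome 9, 114784635 to 114806126 in GRCh38), rose by 3.99 (SE 0.13), from 3.15 ± 0.671 CPM to 50.4 ± 5.49 CPM (mean and SD, n = 3). FAM180A rose by 4.09 (SE 0.16), the sterol transporter NPC1L1 by 3.72 (SE 0.18) and AKR1C1 by 2.57 (SE 0.16). The largest rise under the rule was MIR4432HG, a microRNA host transcript, at 4.10 (SE 0.31). Among the largest falls were the chromatin assembly factor CHAF1B at -1.35 (SE 0.079), DNA ligase 1 (LIG1) at -1.52 (SE 0.068), PDK1 at -1.49 (SE 0.11), the recombination factor RAD51AP1 at -1.49 (SE 0.080) and SREBF1, which encodes the lipid-synthesis regulator SREBP1 (chromosome 17, 17810399 to 17837002), at -1.39 (SE 0.041). SREBF1 went from 132 ± 3.65 CPM to 50.3 ± 1.70 CPM, with an adjusted p of 2.96e-22. The highest adjusted p of these 10 genes was 2.27e-12 (MIR4432HG), and FSS and static libraries did not overlap in any of them.

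Among 19631 genes tested in DAOY, 3834 rose and 3952 fell (edgeR, adjusted p under 0.05), 761 and 280 of them by 2-fold or more. The called genes were 39.7% of those tested, and their median absolute log2 change was 0.37.

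Genes induced by growth-factor and shear signals rose together in DAOY. Among shear-responsive transcription factors 11 of 15 tested members rose and 1 fell, or 12 and 2 when adjusted over the list alone (camera adjusted p = 0.00156, and adjusted p = 0.273 with an estimated correlation). KLF2 rose by 0.50 (SE 0.10), KLF4 by 0.33 (SE 0.053), KLF10 by 0.39 (SE 0.053) and JUN by 0.32 (SE 0.049). Among immediate early genes, which share members with the former list, 15 of 21 tested members rose and 1 fell, or 16 and 1 when adjusted over the list alone (camera adjusted p = 8.75e-05, and adjusted p = 0.218 with an estimated correlation). The nuclear receptor NR4A2 rose by 1.07 (SE 0.094) and the anti-apoptotic MCL1 by 0.52 (SE 0.037). FOSB, JUNB, DUSP1 and NR4A3 of the immediate early list were at 0 in all 12 libraries and were not tested. Of the feedback genes of MAP kinase signalling 13 of 19 tested members rose and 1 fell, or 13 and 1 when adjusted over the list alone (camera adjusted p = 3.98e-05, and adjusted p = 0.109 with an estimated correlation), with the receptor EPHA2 at 0.94 (SE 0.051), the phosphatase DUSP4 at 0.88 (SE 0.050) and PHLDA1 at 0.72 (SE 0.036). FOS rose by 0.31 (SE 0.12), with adjusted p = 0.0421. The FOS call was lost with DESeq2 (adjusted p = 0.0683), without a count filter (0.0621) and without DAOY FSS replicate 1 (0.0922) or 2 (0.175) or DAOY static replicate 1 (0.0519) or 2 (0.284), with 0.0233 to 0.284 over all alternatives. Its value was 0.18 without DAOY static replicate 2.

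Notch, inflammatory and angiogenic genes rose as well. Among Notch genes 10 of 16 tested members rose and 0 fell, or 11 and 0 when adjusted over the list alone (camera adjusted p = 0.000699, and adjusted p = 0.178 with an estimated correlation). The ligands DLL1 and JAG1 rose by 0.94 (SE 0.079) and 0.50 (SE 0.047), the effector HEY1 by 0.57 (SE 0.055) and cyclin D1 (CCND1) by 0.75 (SE 0.056). In the NF-kB and inflammatory cytokine list 14 of 24 tested members rose and 2 fell, or 14 and 2 when adjusted over the list alone (camera adjusted p = 0.00142, and adjusted p = 0.215 with an estimated correlation). The chemokines CXCL8 and CCL2 rose by 1.06 (SE 0.13) and 0.90 (SE 0.087), and the prostaglandin synthase PTGS2 by 0.63 (SE 0.067). Among angiogenic and growth factors 15 of 26 tested members rose and 2 fell, or 15 and 2 when adjusted over the list alone (camera adjusted p = 0.00237, and adjusted p = 0.109 with an estimated correlation), with PDGFA at 0.87 (SE 0.066), NRP2 at 0.54 (SE 0.040) and VEGFA at 0.53 (SE 0.044), while PDGFC fell, at -0.46 (SE 0.047).

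Chaperones and ion carriers rose in DAOY too. In the heat shock list 10 of 14 tested members rose and 1 fell, or 10 and 1 when adjusted over the list alone (camera adjusted p = 9.95e-09, and adjusted p = 0.144 with an estimated correlation). HSPH1 rose by 1.33 (SE 0.040), HSPA1A by 1.27 (SE 0.044) and the cochaperone DNAJA1 by 0.90 (SE 0.038). Among ion and solute carriers 13 of 24 tested members rose and 5 fell, or 13 and 6 when adjusted over the list alone (camera adjusted p = 0.0315, and adjusted p = 0.495 with an estimated correlation). SGK1, a kinase that promotes sodium uptake, rose by 1.32 (SE 0.056), ATP1B1 by 1.23 (SE 0.050) and AKR1B1 by 0.70 (SE 0.049), and SLC6A6 fell, at -0.72 (SE 0.052). The carrier call was lost with a replicate block (adjusted p = 0.0588) and without DAOY FSS replicate 3 (0.0561) or DAOY static replicate 3 (0.0594), with 0.00890 to 0.495 over all alternatives.

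Replication, mitosis and lipid synthesis genes fell in DAOY. In the G1/S and DNA replication list 0 of 28 tested members rose and 26 fell, or 0 and 27 when adjusted over the list alone (camera adjusted p = 3.77e-15, and adjusted p = 0.0666 with an estimated correlation), with RRM2 at -0.98 (SE 0.044), MCM5 at -0.92 (SE 0.047) and E2F1 at -0.93 (SE 0.065). In the G2/M and mitosis list 0 of 31 tested members rose and 25 fell, or 0 and 25 when adjusted over the list alone (camera adjusted p = 5.01e-12, and adjusted p = 0.232 with an estimated correlation). The proliferation marker MKI67 changed by -0.70 (SE 0.042) and the kinetochore motor CENPE by -0.69 (SE 0.045). In the fatty acid synthesis list 1 of 15 tested members rose and 11 fell, or 1 and 11 when adjusted over the list alone (camera adjusted p = 0.000102, and adjusted p = 0.0666 with an estimated correlation). Besides SREBF1, the desaturases SCD and FADS2 changed by -0.59 (SE 0.035) and -0.45 (SE 0.038) and the acetyl-CoA carboxylase ACACA by -0.49 (SE 0.047). In the cholesterol synthesis list 3 of 24 tested members rose and 13 fell, or 3 and 14 when adjusted over the list alone (camera adjusted p = 0.0102, and adjusted p = 0.146 with an estimated correlation), with mevalonate kinase (MVK) at -0.90 (SE 0.080), LSS at -0.58 (SE 0.048) and DHCR7 at -0.41 (SE 0.048).

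Respiratory chain and cilium genes were also lower. In the oxidative phosphorylation list 3 of 26 tested members rose and 14 fell, or 3 and 15 when adjusted over the list alone (camera adjusted p = 0.0202, and adjusted p = 0.642 with an estimated correlation), with UQCRC1 at -0.40 (SE 0.038) and NDUFV1 at -0.42 (SE 0.043). In the primary cilium list 2 of 24 tested members rose and 10 fell, or 2 and 10 when adjusted over the list alone (camera adjusted p = 0.0326, and adjusted p = 0.381 with an estimated correlation), with CEP290 at -0.84 (SE 0.066) and BBS4 at -0.87 (SE 0.10). The cilium call was lost with a stricter filter (adjusted p = 0.0756) and without DAOY FSS replicate 3 (0.0561) or DAOY static replicate 3 (0.0594), with 0.0107 to 0.381 over all alternatives. GLI1, a transcription factor of Hedgehog signalling, rose by 0.31 (SE 0.12), with adjusted p = 0.0315. The GLI1 call was lost with DESeq2 (adjusted p = 0.0517), with TPM and a pseudocount of 0.1 (0.219), and without DAOY FSS replicate 1 (0.205) or 2 (0.0533) or DAOY static replicate 1 (0.101) or 2 (0.103), with 0.0086 to 0.219 over all alternatives. The mechanically gated channel PIEZO1 changed by -0.17 (SE 0.051) in DAOY (adjusted p = 0.00719), a call lost without DAOY FSS replicate 1 (0.0700, with 0.00232 to 0.0700 over all alternatives), and measured 0.07 (SE 0.049) in ONS76 (adjusted p = 0.307). PIEZO2 measured 0.31 (SE 0.35) in ONS76 and 0.13 (SE 0.13) in DAOY (adjusted p = 0.560 and 0.481). The glucose transporter SLC2A1 measured 0.09 (SE 0.040) and 0.06 (SE 0.041) (adjusted p = 0.108 and 0.269), and its ONS76 value passed the threshold with ONS76 libraries alone (0.0490) and with TPM (0.0313 and 0.0308, with 0.0308 to 0.306 over all alternatives).

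**Figure D1:**
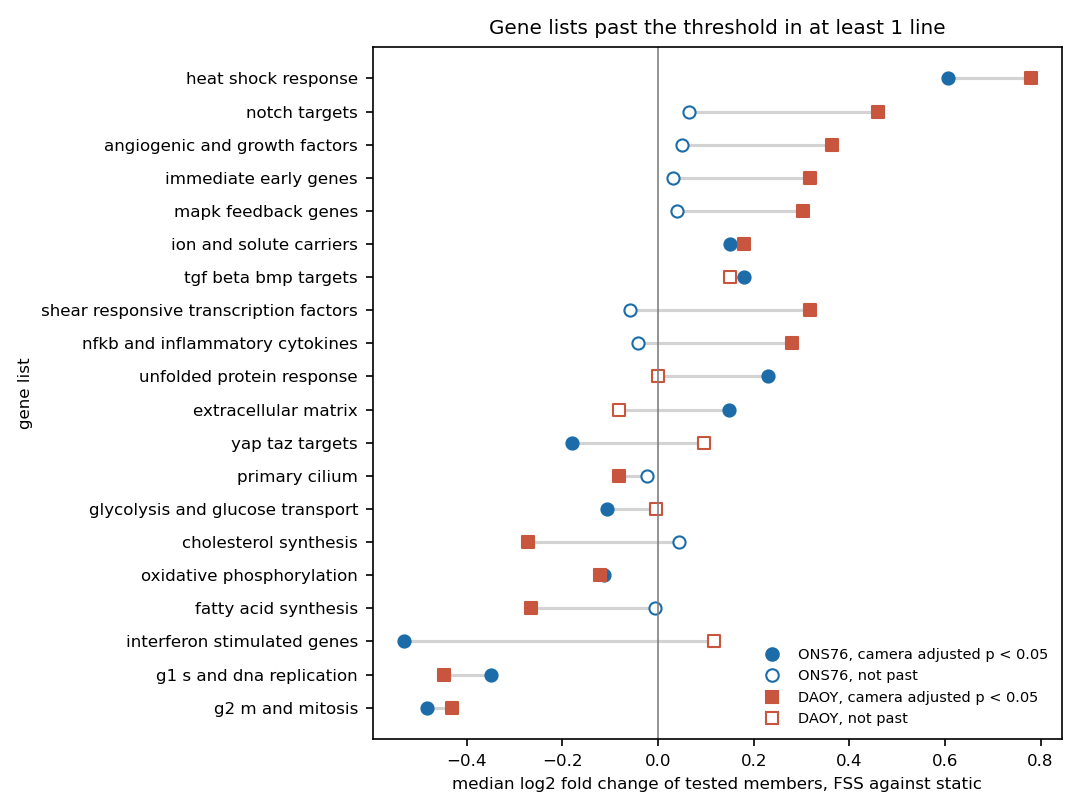
Median log2 fold change (x axis, FSS against static) of the tested members of each gene list (y axis) that passed the camera threshold in at least 1 line, for ONS76 (circles) and DAOY (squares), filled where the list passed in that line. The heat shock list lies farthest to the right in both lines, at 0.61 and 0.78, and the G2/M list lies at -0.48 and -0.43.

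A core of genes changed in the same direction under FSS in both lines. AKR1C1, the neuroendocrine secretory protein SCG2 (1.37 in ONS76, 1.83 in DAOY), the GTPase RAB17 (2.31 in DAOY, and from 2.31 ± 0.152 CPM to 5.50 ± 0.730 CPM in ONS76), the activity-induced ARC (1.00, 1.37) and HSPH1 rose most under the naming rule. PDK1, RBM3, the carboxypeptidase CPA4 (-1.18, -1.14), RAD51AP1 and the antisense transcript ACVR2B-AS1 (-1.09, -1.33) fell most. The strand setting of the counting is not given in the sources used here, so reads of an antisense transcript cannot be told apart from those of its partner. CIRBP, the other cold-inducible RNA-binding protein, named after its values were seen, changed by -0.86 (SE 0.043) in ONS76 and -1.17 (SE 0.045) in DAOY. VEGFA rose in both (0.48 and 0.53). RBM3 went from 458 ± 9.76 CPM to 154 ± 4.80 CPM in ONS76 and from 144 ± 3.98 CPM to 64.8 ± 3.83 CPM in DAOY (mean and SD, n = 3).

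Of 3406 genes called in both lines, 2924 (85.8%) changed in the same direction. Of these, 636 also passed the test of a difference between the lines, so their responses differed in size, among them RAB17, HSPH1 and RBM3. AKR1C1, SCG2 and RAD51AP1 passed it too, with calls that some alternatives ended. That of AKR1C1 was lost with TPM and a pseudocount of 1 (adjusted p = 0.667, with 2.71e-08 to 0.667 over all alternatives). That of SCG2 was lost without DAOY FSS replicate 1 or 2, any DAOY static replicate, ONS76 FSS replicate 1 or 3 or ONS76 static replicate 1 or 2 (0.0511 to 0.118, with 0.000142 to 0.359 over all). That of RAD51AP1 was lost without DAOY FSS replicate 1 or 3, DAOY static replicate 1 or 3, ONS76 FSS replicate 3 or ONS76 static replicate 2 (0.0559 to 0.155, with 0.00954 to 0.155 over all). Both lines raised 1361 genes, where independent lists would share 541 (odds ratio 5.62, 95% interval 5.15 to 6.13), and lowered 1563, where independent lists would share 551 (odds ratio 8.10, 7.41 to 8.85, Fisher's exact test in each case, with p below the smallest number the software can write). The contrasts share no library. Across all tested genes Pearson's r of the log2 fold changes was 0.23 and Spearman's rho 0.33, and r was 0.61 over genes called in both; genes are not independent replicates. Of the 20 lists that passed camera in at least 1 line, 5 passed in both: heat shock, ion and solute carriers, oxidative phosphorylation, G1/S and G2/M. With an estimated correlation 0 of them passed in either line (adjusted p = 0.0666 to 0.642). With the preset correlation, splits of the libraries other than the real one also passed up to 5 lists in ONS76 and 11 in DAOY. Those splits keep part of the FSS difference, so they do not show how many lists would pass without FSS. For lists that passed in ONS76 alone, camera adjusted p in DAOY was 0.896 for the unfolded protein response, 0.0684 for TGF-beta and BMP targets, 0.228 for extracellular matrix, 0.362 for interferon-stimulated genes, 0.281 for YAP/TAZ targets and 0.741 for glycolysis. For those that passed in DAOY alone, it was 0.229 in ONS76 for shear-responsive transcription factors, 0.753 for immediate early genes, 0.203 for MAP kinase feedback, 0.913 for Notch, 0.678 for NF-kB, 0.663 for angiogenic, 0.523 for fatty acid, 0.271 for cholesterol and 0.806 for cilium genes. Leaving out static ONS76 libraries 1 and 2, an alternative chosen after the data were seen, left 1900 genes changed the same way.

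**Figure D2:**
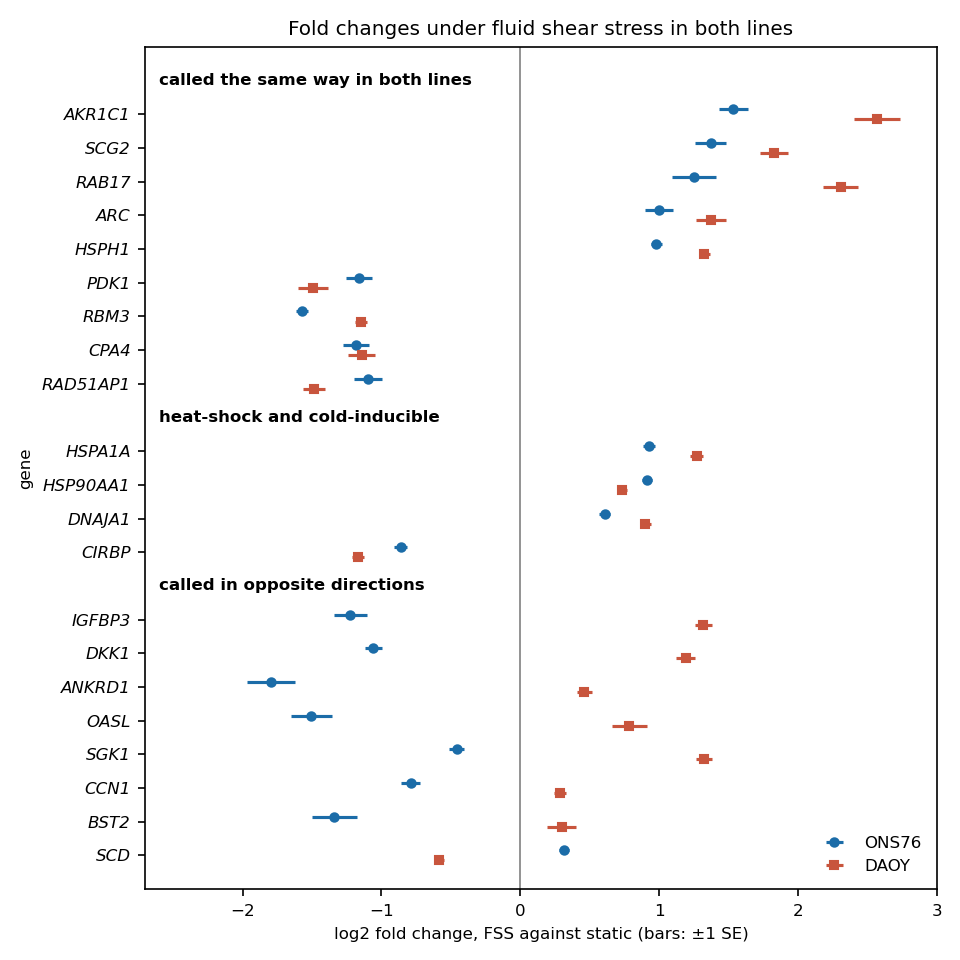
Log2 fold change (x axis, FSS against static, bars ±1 SE, 3 libraries per group) of named genes (y axis) in ONS76 (circles) and DAOY (squares). HSPH1 lies at 0.98 and 1.33 and RBM3 at -1.57 and -1.15, while IGFBP3 lies at -1.22 in ONS76 and 1.32 in DAOY.

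The lines also answered FSS differently. IGFBP3 fell in ONS76 and rose in DAOY, a difference of log2 fold changes, DAOY minus ONS76, of 2.54 (SE 0.13), with adjusted p = 2.48e-15. The Wnt antagonist DKK1 changed by -1.06 in ONS76 and 1.19 in DAOY (difference 2.25, SE 0.091, adjusted p = 8.05e-18), SGK1 by -0.46 and 1.32 (difference 1.78, SE 0.077), ANKRD1 by -1.79 and 0.46 (difference 2.26, SE 0.18), and OASL fell in ONS76 and rose by 0.79 in DAOY (difference 2.29, SE 0.19). SREBF1 fell in both, by more in DAOY (difference -1.14, SE 0.056, adjusted p = 3.84e-16), and SCD rose in ONS76 (0.31) and fell in DAOY (difference -0.90, SE 0.050). Adjusted p for SGK1, ANKRD1, OASL and SCD was 1.8e-17, 6.48e-11, 1.76e-10 and 9.42e-15.

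Across the genome 3740 genes differed in their response (edgeR interaction contrast), with 1637 higher and 2103 lower in DAOY, and 529 differing by 2-fold or more. All 482 genes called in opposite directions were among them. Of 6479 genes called in 1 line and not in the other, 2513 passed the test of the difference, so for the other genes a difference between lines was not shown.

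At the level of lists, in a test chosen after the data were seen, 18 of 42 differed between the lines. Shear-responsive transcription factors, immediate early genes, MAP kinase feedback genes, Notch genes, NF-kB and inflammatory genes, interferon-stimulated genes, YAP/TAZ targets, angiogenic factors, heat shock genes, G2/M genes and mitochondrially encoded mRNAs had a higher response in DAOY than in ONS76. For G2/M genes, which fell in both lines, this was a smaller fall at the median in DAOY. Fatty acid synthesis, cholesterol synthesis, unfolded protein response, extracellular matrix, p53, G1/S and primary cilium genes moved lower. Without static ONS76 libraries 1 and 2 the direction for mitochondrially encoded mRNAs turned (adjusted p = 0.435, with 2.02e-05 to 0.623 over its alternatives) and the calls of G1/S (0.122, with 0.00399 to 0.500) and heat shock genes (0.0635, with 0.00555 to 0.500) ended. That fit rests on static ONS76 replicate 3, where mitochondrial transcripts took 0.920% of counts, against 1.40% in replicate 1 and 1.31% in replicate 2. Fatty acid synthesis, with 10 of 15 tested members lower and 0 higher (11 and 2 adjusted over the list alone), held with an estimated correlation (adjusted p = 2.27e-05 by camera, adjusted p = 0.0338 with an estimated correlation). It was the sole list in any comparison to do so. The other 17 lists had adjusted p of 0.0642 (interferon-stimulated genes) to 0.623 (G2/M and mitochondrially encoded mRNAs) with an estimated correlation.

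**Figure D3:**
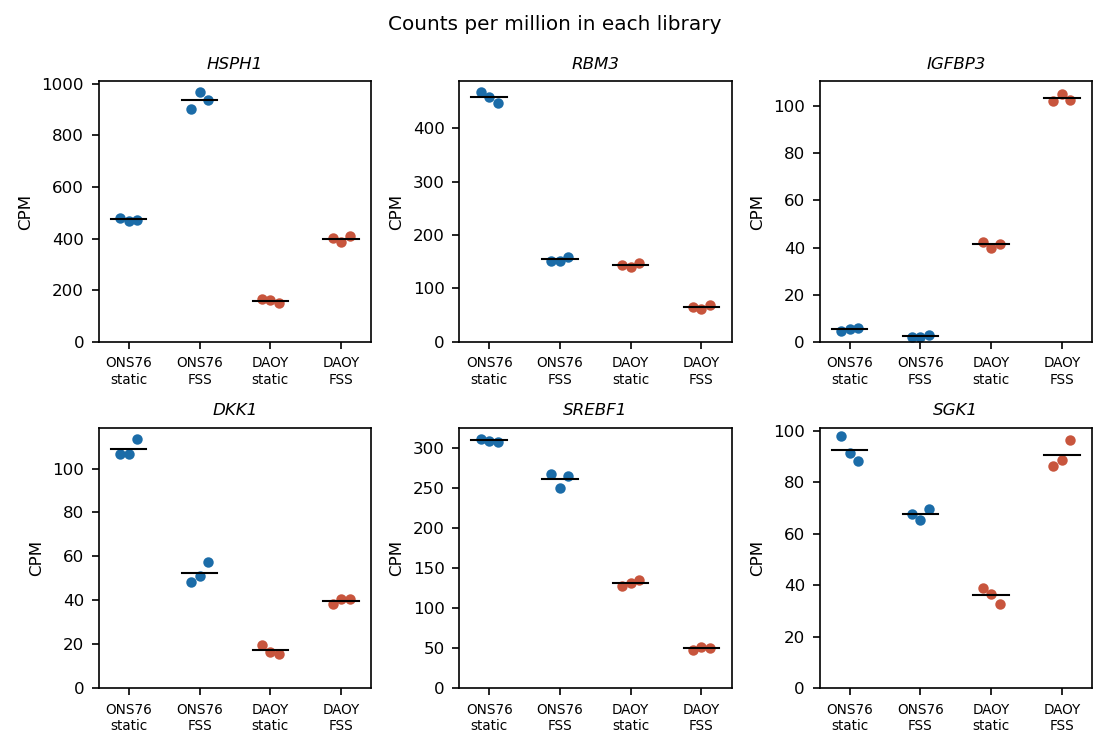
CPM (y axis, from 0) of 6 genes in each of the 12 libraries (points) by line and condition (x axis), with the group mean as a line. DKK1 moves in opposite directions in the lines, from 109 ± 3.94 CPM to 52.4 ± 4.80 CPM in ONS76 and from 17.4 ± 2.19 CPM to 39.8 ± 1.33 CPM in DAOY (mean and SD, n = 3).

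The largest fitted differences between responses fell on genes almost silent in 1 line, where the fitted fold rests on few counts. COL1A2, a chain of type I collagen, had 16 counts in static ONS76 and 0 under FSS, summed over 3 libraries, against 84529 and 132483 in DAOY. LEF1, LONRF3 and CNNM1 had 11, 4 and 6 counts in static ONS76 and 0 under FSS. LINC01139 had 0 and 6, IRX4 1 and 18 and RFPL4A 3 and 32. CLCA2 and KRT13 had 7 and 13 counts in static DAOY and 0 under FSS. MYH7, a cardiac myosin, had 1210 counts in static ONS76, 942 of them in replicate 1 and 266 in replicate 2, and 4 under FSS. Calls were lost without 1 library for MYH7 (DAOY FSS replicate 2, adjusted p = 0.0529), COL1A2 (ONS76 static replicate 1, 0.306), LEF1 (any ONS76 FSS replicate, 0.0524 to 0.0575, or ONS76 static replicate 3, 0.404), LONRF3 (any ONS76 FSS replicate, 0.0557 to 0.0596, or ONS76 static replicate 2, 0.0975) and CNNM1 (any ONS76 FSS replicate, 0.0790 to 0.0859, or ONS76 static replicate 3, 0.366). They were also lost for LINC01139 (ONS76 FSS replicate 2, 0.147, or ONS76 static replicate 1, 0.0559), CLCA2 (DAOY static replicate 2, 0.0908), KRT13 (any DAOY FSS replicate, 0.0734 to 0.0800, or DAOY static replicate 2, 0.187) and IRX4 (ONS76 FSS replicate 2, 0.206, or ONS76 static replicates 1 and 3, 0.110 and 0.0861). RFPL4A kept its call without each library in turn. Over all alternatives adjusted p ran from 3.27e-32 to 0.782 for MYH7, 1.99e-06 to 0.306 for COL1A2, 0.000223 to 0.414 for LEF1, 0.000134 to 0.191 for LONRF3 and 0.00382 to 0.366 for CNNM1. It ran from 0.00613 to 0.172 for LINC01139, 0.00502 to 0.0908 for CLCA2, 0.0120 to 0.623 for KRT13, 0.00551 to 0.468 for IRX4 and 8.98e-05 to 0.138 for RFPL4A.

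Without shear, the 2 lines were far apart. The transcript MIR205HG was at least 2747-fold higher in static ONS76 than in static DAOY and KLHL9, an adaptor of a ubiquitin ligase (chromosome 9, 21329671 to 21335380, GRCh38), at least 2221-fold higher, with 0 counts of either in DAOY. HS3ST1, CTAG2 and PNMA5 were also among the genes most enriched in ONS76, with 6499, 44266 and 47252 counts over 3 libraries against 3, 23 and 27 in DAOY. In the other direction, SPANXB1 was at least 5023-fold, MFAP2, a microfibril protein, at least 4362-fold, MAGEB2 at least 3273-fold, IGFBPL1 at least 2839-fold and MAGEC1 at least 2755-fold higher in static DAOY, with 0 counts in static ONS76. CTAG2, SPANXB1, MAGEB2 and MAGEC1 are cancer-testis antigens of gene families whose near-identical members can exchange reads. Bounds use a floor of 3 counts over the group and cover counting error alone.

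In total 15908 genes differed between the static lines (edgeR, adjusted p under 0.05), 9361 of them by 2-fold or more, with 7433 higher in ONS76 and 8475 higher in DAOY. The balance depended on the scaling: 46.7% of called genes were higher in ONS76, against 44.4% with RLE and 38.3% with upper-quartile factors, with a median log2 fold change of all genes of -0.10, -0.16 and -0.32. With TPM and pseudocounts of 1 and 0.1, tested with limma on 17399 genes, it was 32.8% and 32.6%, with medians of -0.38 and -0.45, and there the test and the genes differ as well as the scaling.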

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

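Tests of single genes for differences between the lines were planned, while those of gene lists, the splits of the libraries and the tests of the chaperone, myosin and zero-count patterns were chosen after the results were seen.

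With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. In fits to 6 libraries the real split gave 2668 risen and 2992 fallen genes in ONS76 and 4076 and 4142 in DAOY, each the only 1 of 10 splits as large, and the highest other split gave 0. Between static lines the real split gave 15843 genes and the highest other 0 (1 of 10 as large). For gene lists the real split gave 10 in ONS76 and 13 in DAOY, against 5 and 11 for the highest other (1 of 10 as large in each). Other splits, with 0 genes called, thus still passed up to 5 and 11 lists. Every other split mixes the compared libraries unevenly, so it keeps part of their difference and widens the spread within its groups. The genes and lists called in other splits therefore do not show what would be called without FSS. The number of lists that pass camera with the preset correlation is thus not set against splits free of FSS. For the 2924 genes changed the same way in both lines, 1 of 100 draws from 200 joint splits was as large, and the highest other gave 482. For the 3740 genes whose response differed, 2 of 100 draws were as large. The highest other, with 7940 genes, keeps both true splits and swaps the labels of 1 line, which turns same-direction genes into opposite ones, and the other 98 draws gave at most 3302. Redrawing labels within a line removes that line's response, so these draws do not bear on whether responses are shared or differ.

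FSS responses differed between DAOY and ONS76 for 1637 genes with a higher response in DAOY and 2103 with a lower one (edgeR, test of the difference). Higher and lower compare the responses, so a higher response can be a smaller fall. Among lists, shear-responsive transcription factors moved higher in DAOY (camera adjusted p = 2.27e-05, adjusted p = 0.157 with an estimated correlation), as did immediate early genes (0.00014, and 0.189 with an estimated correlation), MAP kinase feedback genes (0.00013, 0.126), NF-kB and inflammatory genes (0.00013, 0.145), Notch genes (0.000788, 0.157) and angiogenic factors (0.021, 0.157). Interferon-stimulated genes (2.53e-05, adjusted p = 0.0642 with an estimated correlation), YAP/TAZ targets (0.000884, 0.235), heat shock genes (0.021, 0.500), G2/M genes (0.021, 0.623) and mitochondrially encoded mRNAs (0.0367, 0.623) also had a higher response in DAOY. G2/M genes fell in both lines, with a median log2 fold change of -0.48 in ONS76 and -0.43 in DAOY. Fatty acid synthesis (2.27e-05, adjusted p = 0.0338 with an estimated correlation), cholesterol synthesis (0.000324, 0.0705), unfolded protein response (0.00013, 0.189), extracellular matrix (0.00266, 0.157), p53 (0.000884, 0.0985), G1/S (0.021, 0.500) and cilium genes (0.036, 0.470) moved lower.

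Some of these list differences were lost without 1 library. For G2/M genes this held without DAOY FSS replicate 1 (adjusted p = 0.0514), DAOY static replicate 3 (0.0758), ONS76 FSS replicate 1 (0.158) or ONS76 static replicate 1 (0.149), within a range of 0.00102 to 0.623 over its alternatives. For mitochondrially encoded mRNAs it held without DAOY FSS replicate 1 (0.0877) or 2 (0.0795), DAOY static replicate 1 (0.0653) or 3 (0.0758), ONS76 FSS replicate 1 (0.191), or ONS76 static replicate 1 (0.185) or 2 (0.143), with 2.02e-05 to 0.623 over all. For cilium genes it held without DAOY FSS replicate 3 (0.0668), DAOY static replicate 3 (0.0758), ONS76 FSS replicate 3 (0.0605) or ONS76 static replicate 3 (0.0590), and the call was also lost with a stricter filter (0.0693), with 0.0119 to 0.470 over all. For G1/S genes it held without ONS76 FSS replicate 3 (0.0560, with 0.00399 to 0.500 over all) and for heat shock genes without ONS76 static replicate 1 (0.0595, with 0.00555 to 0.500 over all). Without both static ONS76 libraries 1 and 2 the direction for mitochondrially encoded mRNAs turned (0.435), and the calls of G1/S (0.122) and heat shock genes (0.0635) ended.

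Named genes whose responses differed are given as the log2 fold change in DAOY minus that in ONS76, each past the edgeR threshold for the difference. Signalling and inflammatory genes moved higher in DAOY: CCL2 by 2.55, CXCL8 by 0.87, IGFBP3 by 2.54, DKK1 by 2.25, SGK1 by 1.78, KLF2 by 0.56, KLF4 by 0.27, KLF10 by 0.69, MCL1 by 0.40, PHLDA1 by 0.69, EPHA2 by 0.75 and DUSP4 by 0.43. Notch and growth factor genes did so too, with DLL1 at 0.85, JAG1 at 0.36, HEY1 at 0.39, CCND1 at 0.71, PDGFA at 0.96 and NRP2 at 0.51, while PDGFC was at -0.43. YAP/TAZ and interferon-stimulated genes showed the same direction, with ANKRD1 at 2.26, CCN1 at 1.07, OASL at 2.29, BST2 at 1.64 and ISG15 at 0.85.

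Differences in matrix, adhesion and transport genes went both ways. SERPINE2 was at 0.88, COL5A1 at 0.47, CLDN4 at 1.51, CDH5 at 1.56, ATP1B1 at 0.59 and LRRC8A at 0.40. Lower in DAOY were MMP2 at -1.10, VCAN at -0.68, HSPG2 at -0.69, EPHB3 at -0.72, AQP3 at -0.98, SLC6A6 at -0.22, STIM1 at -0.63 and PIEZO1 at -0.24. In the BMP and Wnt groups BMP4 was at -0.66, BMP7 at -1.53, PMEPA1 at -0.28 and LGR5 at -1.85.

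Metabolic, chaperone and cell-cycle genes also differed. SREBF1 was at -1.14, SCD at -0.90, FADS2 at -0.67, ACACA at -0.54, MVK at -0.96, LSS at -0.53 and DHCR7 at -0.44, and LDHA was at 0.36 and the metallothionein MT2A at 0.57. HSPA5 was at -0.42, HSP90B1 at -0.34, XBP1 at -0.49 and HSP90AA1 at -0.18, while HSPH1 was at 0.35, HSPA1A at 0.34 and DNAJA1 at 0.29. RBM3 was at 0.42 and CIRBP at -0.31. In the cell cycle CDK1 was at 0.64, AURKB at 0.24, TOP2A at 0.22, MKI67 at -0.43, LIG1 at -0.84, CHAF1B at -0.59, MCM5 at -0.45, RRM2 at -0.22, RAD51AP1 at -0.39, CEP290 at -0.48 and CDKN1A at -0.50. Among the genes with the largest responses MIR4432HG was at 3.97, FAM180A at 3.57, NPC1L1 at 1.46, AKR1C1 at 1.03, RAB17 at 1.06, SCG2 at 0.46, S100P at 1.11 and NAGLU at 0.94, and ARRB1 at -1.66 and IGFBP5 at -1.02. For genes near 0 counts in 1 group the fitted difference depends on edgeR's prior count: MYH7 at 8.54, COL1A2 at 6.14, LEF1 at 5.11, LONRF3 at 4.68, CNNM1 at 4.49, LINC01139 at -4.94, CLCA2 at -4.74, KRT13 at -4.21, IRX4 at -3.32 and RFPL4A at -3.16. Without 1 library some of these moved by over 1.5 times: COL1A2 to 3.07 (ONS76 static replicate 1), LEF1 to 2.46 and CNNM1 to 2.68 (ONS76 static replicate 3), IRX4 to -5.30 (ONS76 static replicate 2), KRT13 to -2.76 (DAOY static replicate 2) and NPC1L1 to 0.43 (ONS76 static replicate 3).

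Some gene differences were lost without 1 library. AURKB lost its call without DAOY FSS replicate 1 or 2, DAOY static replicate 3, ONS76 FSS replicate 1 or 2 or ONS76 static replicate 1 or 3 (adjusted p = 0.0516 to 0.0942, with 0.0112 to 0.0942 over all alternatives). BMP4 lost it without ONS76 static replicate 2 (0.0607, with 0.000452 to 0.554 over all), and HSP90AA1 and RRM2 without ONS76 FSS replicate 2 (0.0551 and 0.0632, with 0.000698 to 0.0555 and 0.00141 to 0.148 over all). KLF4 lost it without DAOY FSS replicate 3, DAOY static replicate 2 or ONS76 static replicate 3 (0.0543 to 0.0641, with 0.00226 to 0.0767 over all). NAGLU lost it without DAOY FSS replicate 1 or 3, DAOY static replicate 1 or 2, ONS76 FSS replicate 2 or ONS76 static replicate 2 (0.0592 to 0.117, with 0.00286 to 0.145 over all). NPC1L1 lost it without DAOY FSS replicate 1 or 3, DAOY static replicate 2 or 3, any ONS76 FSS replicate or ONS76 static replicate 2 or 3 (0.0512 to 0.789, with 2.95e-06 to 0.789 over all) and with RLE factors (0.0504), and its difference was 0.43 without ONS76 static replicate 3. RAD51AP1 lost it without DAOY FSS replicate 1 or 3, DAOY static replicate 1 or 3, ONS76 FSS replicate 3 or ONS76 static replicate 2 (0.0559 to 0.155, with 0.00954 to 0.155 over all). SCG2 lost it without DAOY FSS replicate 1 or 2, any DAOY static replicate, ONS76 FSS replicate 1 or 3 or ONS76 static replicate 1 or 2 (0.0511 to 0.118, with 0.000142 to 0.359 over all), and also with DESeq2 (0.0524). SLC6A6 lost it without DAOY FSS replicate 2, DAOY static replicate 2, ONS76 FSS replicate 1 or ONS76 static replicate 2 or 3 (0.0678 to 0.109, with 0.00426 to 0.109 over all). With TPM and a pseudocount of 1 the calls of AKR1C1 (0.667, with 2.71e-08 to 0.667 over all) and CDH5 (0.171, with 2.42e-06 to 0.171 over all) ended. The PIEZO1 difference lost its call with TPM and a pseudocount of 0.1 (0.0588) and without static ONS76 libraries 1 and 2 (0.185, with 0.00544 to 0.185 over all), and that of HEY1 without these libraries (0.0543, with 9.75e-06 to 0.0543 over all).

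Heat shock genes were higher and the cold-inducible RBM3 and CIRBP lower under FSS in both lines. Reads shared between HSPA1A and HSPA1B do not account for this, since 8 of the 12 other tested members were also higher in both. A warmer medium on the shaker may give such values, as 10 of 14 heat shock members were higher in both lines and both cold-inducible genes lower, but every sheared plate was also a shaken one, so platform warmth and shear cannot be told apart here. Evaporation and a more concentrated medium stays open too: of 7 tested tonicity-responsive genes 3 were higher in both lines (AKR1B1, SLC38A2 and S100A4) and 1, SLC6A6, lower in both. A response to shear itself is an open biological explanation that was not tested apart from the shaker.

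The cardiac myosin genes MYH6 and MYH7 and the tropomyosin gene TPM1 stood apart in static ONS76 libraries 1 and 2, with 1521 and 500 counts of MYH6 there, 2 in replicate 3 and at most 5 in any ONS76 FSS library. ACTN2, a sarcomere gene, followed them, with 51 and 30 counts there and at most 3 in the other 4 ONS76 libraries. Another 14 heart muscle genes, each with counts in at least 1 library, summed to a mean of 50 counts in these libraries against 46 to 95 in the other 4 (90.5 against 49 to 95 with ACTN2). TNNI3, TNNC1, MYL2 and MYL3 had at most 6 counts each in libraries 1 and 2. These genes argue against RNA from heart muscle cells, but ACTN2 goes with it. TNNT2, ACTC1, MYL7 and PLN were at 0 in all 12 libraries and cannot be read, so heart muscle RNA is not excluded. RNA or reads from the DAOY libraries are argued against by MYH6, whose highest DAOY count was 9. No group of the design separates these libraries, so no biological explanation was tested, and the origin of the transcripts stays open.

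Some genes that every cell uses were listed at 0 in all 12 libraries, among them RPL15, RPL32, SDHA, NDUFA9, NDUFB5, NDUFB8 and ATP5PO, the 7 of 77 respiratory and ribosomal list members at 0. Silence in both lines is argued against by the median of 645.7 CPM over the other 70 members. The lowest of those 70 lay at 0.0167 CPM, so values near 0 were not confined to the genes at 0. Reads left unassigned where genes overlap in GENCODE 29 are argued against as the sole cause for these 7. SDHA and NDUFB5 overlap no other gene there, and NDUFB8, the least free of the 7, keeps 51.5% of its exon length free. Of all 66 list genes at 0 of 958, 24 overlap no other gene, 42 overlap one on either strand and 22 on the same strand. Each keeps at least 19.8% of its exon length free. Whether others of the 66 are silent in these lines was not tested, so their zeros need not be lost reads. A part played by overlap stays open. Of list genes at 0, 36.4% overlapped no other gene, against 57.0% of the others. Of protein-coding genes almost covered by others 25.2% were at 0, against 12.9% of those free of overlap. Overlap in the annotation behind the counts, which is not given in the sources used here, cannot be told apart from other losses. The expression of CCN2 and other genes at 0 cannot be read from these counts.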

How the results depend on the processing

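Leaving out static ONS76 libraries 1 and 2, and the alternatives for list differences between the lines, were chosen after the data were seen, and the others were planned. That exclusion left 1558 risen and 1818 fallen genes in ONS76 and 1900 changed the same way in both lines, with a group of 1 library in the fit. It also turned the direction of the difference for mitochondrially encoded mRNAs (adjusted p = 0.4353, with 2.02e-05 to 0.623 over its alternatives) and ended the calls of G1/S (0.122) and heat shock genes (0.0635). It ended 13 difference calls of named genes: BMP4 (-0.24 against -0.66), MYH7 (1.13 against 8.54), PIEZO1 (-0.18 against -0.24), HEY1, COL1A2, HSP90AA1, IRX4, LINC01139, LONRF3, NAGLU, RAD51AP1, RRM2 and SCG2 (adjusted p = 0.0543 to 0.782, with 3.27e-32 to 0.782 over their alternatives). With an estimated correlation 0 lists passed in ONS76, 0 in DAOY and 1 for the difference, against 11, 14 and 18. Fry, which tests another question, passed 27, 29 and 26. With the 500 most variable genes the first principal components held 98.829% and 0.27022% of the variance. With TPM and a pseudocount of 1 the differences of IRX4 (0.19535, adjusted p = 0.468) and KRT13 (0.53734, adjusted p = 0.0332) turned, with 0.00551 to 0.468 and 0.012 to 0.623 over their alternatives, and with TPM and a pseudocount of 1 or 0.1 calls of differences also ended for AKR1C1, BMP4, CDH5, CNNM1, COL1A2, KLF4, LEF1, NAGLU, PIEZO1, RFPL4A, SCG2 and SLC6A6 (adjusted p = 0.0565 to 0.667, with 2.71e-08 to 0.667 over their alternatives). The cause was not tested for any of these. The static ONS76 library kept in the exclusion, replicate 3, differed most from the others of its group. Calls lost there therefore cannot be traced to libraries 1 and 2.

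Every other count stayed within 1.5 times its value. Over DESeq2, scaling, filter, line-only and TPM alternatives, risen and fallen genes ran from 2654 to 2990 and 2138 to 2862 in ONS76 and from 3187 to 4307 and 3559 to 4242 in DAOY. Leaving out 1 library at a time gave 2247 to 2797 and 2187 to 2822 in ONS76, 3188 to 3909 and 3449 to 4038 in DAOY, 3283 to 3631 for the difference, 2448 to 2776 shared and 15647 to 16200 between static lines. Replicate numbers shared by the groups did not pair the libraries: same-number correlations ran from -0.0276 to 0.0165, and a library's best partner had its own number for replicate 1 alone in each line. With the number as a replicate block 2710 genes rose and 2687 fell in ONS76 and 3765 and 3902 in DAOY, and 9, 14 and 17 lists passed. The block ended the calls of matrix (adjusted p = 0.104) and glycolysis genes (0.0591) in ONS76, of carriers in DAOY (0.0588) and of the mitochondrial mRNA difference (0.0748). The differences of genes near 0 counts in 1 line rest on few counts.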

Other observations

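Gene lists that passed camera's threshold in neither line still held called genes. Over all tested genes 28.0% were called in ONS76 and 39.7% in DAOY, so called members are not by themselves a result about a list. All of these lists were fixed beforehand, so their tests were planned. The stretch of chromosome 9 and the features named last were chosen after their values were seen. Of 24 mechanosensitive channels, 7 rose and 1 fell in ONS76 (7 and 1 adjusted over the list alone, camera adjusted p = 0.299) and 3 rose and 7 fell in DAOY (4 and 7 adjusted over the list alone, camera adjusted p = 0.654). The volume-regulated channel subunit LRRC8A rose in DAOY (0.44). Of 28 calcium signalling genes, 5 rose and 3 fell in ONS76 (5 and 3 adjusted over the list alone, camera adjusted p = 0.997) and 5 rose and 8 fell in DAOY (7 and 8 adjusted over the list alone, camera adjusted p = 0.434), and the store sensor STIM1 fell in DAOY (-0.65). Of 19 targets of the actin-regulated factors SRF and MRTF, 3 rose and 5 fell in ONS76 (3 and 5 adjusted over the list alone, camera adjusted p = 0.229) and 2 rose and 5 fell in DAOY (2 and 5 adjusted over the list alone, camera adjusted p = 0.206). Of 28 integrin and focal adhesion genes, 7 rose and 4 fell in ONS76 (7 and 4 adjusted over the list alone, camera adjusted p = 0.297) and 6 rose and 8 fell in DAOY (6 and 8 adjusted over the list alone, camera adjusted p = 0.741), with ITGA2 up (0.37 and 0.42) and ITGA3 down (-0.44 and -0.52) in both. Of 20 mesenchymal genes and transcription factors of epithelial-mesenchymal transition, 5 rose and 3 fell in ONS76 (6 and 3 adjusted over the list alone, camera adjusted p = 0.229) and 8 rose and 5 fell in DAOY (9 and 5 adjusted over the list alone, camera adjusted p = 0.490). Of 14 epithelial genes, 3 rose and 0 fell in ONS76 (3 and 0 adjusted over the list alone, camera adjusted p = 0.265) and 3 rose and 3 fell in DAOY (3 and 3 adjusted over the list alone, camera adjusted p = 0.896), with the tight junction gene CLDN4 up in both (0.30 and 1.80). Of 25 matrix proteases and inhibitors, 11 rose and 3 fell in ONS76 (11 and 3 adjusted over the list alone, camera adjusted p = 0.0525) and 8 rose and 5 fell in DAOY (8 and 5 adjusted over the list alone, camera adjusted p = 0.265). The gelatinase gene MMP2 rose in ONS76 (0.95) and fell in DAOY (-0.15), and SERPINE2 rose in both (0.47 and 1.35). The CLDN4 call in ONS76 was lost without ONS76 FSS replicate 2 (adjusted p = 0.165), ONS76 static replicate 2 (0.0824) or 3 (0.0556), or both static libraries 1 and 2 (0.129, with 0.00987 to 0.165 over all alternatives), and the MMP2 call in DAOY with TPM (0.0576 and 0.0734, with 0.000851 to 0.0734 over all).

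Developmental and neural lists were mixed too. Of 17 genes of the Sonic hedgehog pathway, 1 rose and 1 fell in ONS76 (1 and 0 adjusted over the list alone, camera adjusted p = 0.913) and 7 rose and 2 fell in DAOY (7 and 2 adjusted over the list alone, camera adjusted p = 0.206). Of 16 Wnt pathway genes, 8 rose and 3 fell in ONS76 (8 and 3 adjusted over the list alone, camera adjusted p = 0.125) and 4 rose and 1 fell in DAOY (4 and 1 adjusted over the list alone, camera adjusted p = 0.362). The stem cell receptor LGR5 rose in ONS76 (2.33), and NOTUM, a secreted Wnt inhibitor, rose in both (1.46 and 1.59). Of 31 axon guidance genes, 13 rose and 6 fell in ONS76 (14 and 7 adjusted over the list alone, camera adjusted p = 0.203) and 8 rose and 10 fell in DAOY (9 and 10 adjusted over the list alone, camera adjusted p = 0.992), with EPHB3 up in both (1.14 and 0.42). Of 13 medulloblastoma and neural progenitor genes, 3 rose and 2 fell in ONS76 (6 and 2 adjusted over the list alone, camera adjusted p = 0.229) and 4 rose and 1 fell in DAOY (4 and 1 adjusted over the list alone, camera adjusted p = 0.130), with the transcription factor SOX4 up in both (0.65 and 0.77). Of 11 immune, endothelial and blood markers, 2 rose and 0 fell in ONS76 (2 and 0 adjusted over the list alone, camera adjusted p = 0.368) and 4 rose and 1 fell in DAOY (4 and 1 adjusted over the list alone, camera adjusted p = 0.147), and the endothelial adhesion gene PECAM1 rose in both (0.77 and 1.04) and CDH5 as well (0.43 and 1.99). In ONS76 the NOTUM call was lost without static libraries 1 and 2 (adjusted p = 0.0875, with 4.81e-05 to 0.0875 over all alternatives) and the CDH5 call with TPM and a pseudocount of 0.1 (0.0626, with 0.000108 to 0.0626 over all).

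Stress and metabolic lists gave similar pictures. Of 24 hypoxia targets, 7 rose and 5 fell in ONS76 (7 and 5 adjusted over the list alone, camera adjusted p = 0.663) and 9 rose and 4 fell in DAOY (9 and 4 adjusted over the list alone, camera adjusted p = 0.130). Among 27 genes of the integrated stress response, 6 rose and 6 fell in ONS76 (6 and 7 adjusted over the list alone, camera adjusted p = 0.753) and 9 rose and 3 fell in DAOY (9 and 3 adjusted over the list alone, camera adjusted p = 0.383). Among 21 NRF2 targets, 5 rose and 8 fell in ONS76 (5 and 8 adjusted over the list alone, camera adjusted p = 0.861) and 9 rose and 4 fell in DAOY (9 and 6 adjusted over the list alone, camera adjusted p = 0.362). Among 5 metallothioneins and zinc genes, 0 rose and 1 fell in ONS76 (0 and 1 adjusted over the list alone, camera adjusted p = 0.229) and 0 rose and 2 fell in DAOY (0 and 2 adjusted over the list alone, camera adjusted p = 0.0684), with MT2A down in ONS76 (-0.64). Among 20 p53 targets, 6 rose and 3 fell in ONS76 (7 and 3 adjusted over the list alone, camera adjusted p = 0.229) and 3 rose and 9 fell in DAOY (3 and 10 adjusted over the list alone, camera adjusted p = 0.0554), with CDKN1A up in ONS76 (0.54) and CCNG1 down in both (-0.50 and -0.60). Among 23 apoptosis regulators, 6 rose and 2 fell in ONS76 (7 and 2 adjusted over the list alone, camera adjusted p = 0.0509) and 8 rose and 4 fell in DAOY (9 and 5 adjusted over the list alone, camera adjusted p = 0.383). Among 22 lysosome and autophagy genes, 5 rose and 0 fell in ONS76 (5 and 0 adjusted over the list alone, camera adjusted p = 0.137) and 6 rose and 5 fell in DAOY (6 and 6 adjusted over the list alone, camera adjusted p = 0.863). Among 43 cytosolic ribosomal protein genes, 0 rose and 3 fell in ONS76 (0 and 1 adjusted over the list alone, camera adjusted p = 0.378) and 3 rose and 8 fell in DAOY (3 and 8 adjusted over the list alone, camera adjusted p = 0.206). Among 13 mitochondrially encoded mRNAs, 0 rose and 1 fell in ONS76 (0 and 0 adjusted over the list alone, camera adjusted p = 0.781) and 9 rose and 0 fell in DAOY (10 and 0 adjusted over the list alone, camera adjusted p = 0.0684). Mitochondrial transcripts took 1.17% ± 0.136 of counts in ONS76 under FSS and 1.21% ± 0.257 in static ONS76, and 0.799% ± 0.0556 and 0.700% ± 0.0230 in DAOY (mean and SD, n = 3). Median, mean and test direction of a list did not all share a sign for calcium signalling, fatty acid synthesis, mesenchymal, NRF2, integrated stress response, mitochondrially encoded and other cell type genes in ONS76, nor for NRF2 and unfolded protein response genes in DAOY.

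Genes read in a stretch of chromosome 9 were nearly silent in DAOY. The stretch lies between FOCAD (21072 counts over the ONS76 libraries and 2393 over the DAOY libraries) and CAAP1 (9735 and 5812). From 20999515 to 25812968 in GRCh38, 10 genes with a symbol had at least 10 counts over the libraries of at least 1 line. Genes below that in both lines were left out and cannot be compared. Of the 10 genes, 7 had 0 counts in all DAOY libraries and the highest DAOY total was 82, for MIR31HG. HACD4, KLHL9, DMRTA1 and TUSC1 were the 4 of 5 protein-coding genes at 0. No copy number was measured here.

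The feature with the highest count summed over the DAOY libraries had an identifier and no symbol. It was the top feature of each of them but static replicate 3, where EEF1A1 led with 2.24%. It took 3.13% to 3.21% of counts in the DAOY FSS libraries and 2.21% to 2.64% in the static ones, with a log2 fold change of 0.38 (SE 0.079, edgeR adjusted p = 0.000261). In ONS76 it took 1.19% to 1.61% under FSS and 1.20% to 1.60% without, with a log2 fold change of 0.02 (SE 0.079, adjusted p = 0.895). The haemoglobin transcripts HBA1, HBA2 and HBB ranged from 0 to 224 counts over the 12 libraries.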
